A study of Caenorhabditis elegans with 2 samples.

How the data were processed

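Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole young adult Caenorhabditis elegans of the strain fem-2(b245), with an affinity-purified rabbit polyclonal antibody against KLE-2. KLE-2 is the kleisin subunit of condensin II, one of the condensin complexes that compact and segregate chromosomes. FEM-2 acts in the sex determination pathway and is needed for male development and for sperm production in hermaphrodites. Per the labels, the animals were hermaphrodites with a germline, grown at 20 °C, and the ground frozen tissue was fixed with 1% formaldehyde for 10 minutes, sheared by sonication and incubated with 5 µg of antibody. The series held 1 ChIP library and 1 input library, both numbered replicate 1. The values analysed came from the 1 peak list deposited under the ChIP library. No values of the input library were analysed here.

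The authors deposited a list of peaks, each with a first base, a last base and a score. Reads were aligned with BWA to ce10, per the submitters' processing notes, and peaks were called with MACS on the WormBase WS220 assembly, per the file headers and columns. Here ce10 is the browser name of WS220. The MACS version, the peak threshold, whether the input served as the control and whether libraries were pooled are not given in the sources used here. The score is the authors' own value per peak, per the file columns, and its scale is not named there. The lowest score was 50.08, and 171 peaks shared exactly 3100, so the score has an apparent lower limit and a ceiling and does not rank the peaks tied there. It was used only to describe, rank and filter peaks within this list. Library depth is unknown, since the list gives no read counts. Intervals from counts of peaks cover counting error only. They treat peaks as independent, although peaks lay closer together than random placement gives, so they can be too narrow.

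With 1 peak list there is no replicate error, and no value below describes the spread between animals, cultures or libraries. Tests therefore asked whether peaks in this list were placed unevenly along the genome. Windows and chromosomes are positions in 1 genome, not biological replicates. Chromosome length was taken as base 1 to the end of the last peak on that chromosome, and each peak was assigned by its midpoint. X and autosomes were compared by peaks per Mb over windows of 1 Mb, with a two-sided permutation test of the X label over the windows (100000 permutations) and a 95% bootstrap interval over windows (10000 draws). Arms (the outer 33.3% of the span at each end) and centers (the rest) were compared with a two-sided exact sign-flip permutation test over the 6 nuclear chromosomes, whose smallest possible p is 0.03125. Peak spacing was compared with 10000 random placements of the same peaks without overlap on their own chromosome. Median score, median width and the share of peaks at the score ceiling were compared between X and autosomes by permuting the X label over windows 10000 times, with Benjamini-Hochberg adjustment over the 3 properties.

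The main comparisons and their tests, the rule for named peaks and most alternatives were fixed before the data were examined. The tests of median score, median width and ceiling share were not in that plan, and the ceiling value was read from the data. The named peaks are the 25 with the highest score, with ties ordered by width and then position. Alternatives were the 3107 peaks with a score above the median, merging of peaks within 500 bp, removal of the widest 1% of peaks, windows of 500 kb and 2 Mb, arms of 25% at each end, covered bases in place of peak number, and neighbour distances of 1 kb and 5 kb. Comparisons of peaks with gene starts, tRNA genes, exons, introns and gene lists were planned but not made. The gene table at hand belongs to the WBcel235 assembly, whose positions cannot be set beside WS220 peaks without conversion, so peaks are named by position and no gene is assigned to them.

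The tests were tried on simulated lists made from the real chromosome spans, 100 lists per setting. With a true X to autosome ratio of 0.5, the mean estimate was 0.501, all 100 lists gave a call at a threshold of 0.05 and the interval held the true value in 90. With even placement, 6 of 100 lists gave a call on X, 6 of 100 gave a call on arms, and 1 of 100 had more close neighbours than every random placement drawn. With an arm to center ratio of 1.5, the mean estimate was 1.49, all 100 lists gave an arm call, and 15 of 100 exceeded every random placement in spacing. With a share of 0.2 of the peaks placed close to another, 100 of 100 did. The simulated lists had equal density on all autosomes and a single peak width, and their tests used fewer permutations and placements. How often the tests call wrongly on a list as uneven as the real one was therefore not measured. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.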

Results

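KLE-2 occupancy in fem-2(b245) young adults was described by 6218 peaks, which covered 4239.7 kb, or 4.23% of the span of the 6 nuclear chromosomes (WS220). Every nuclear chromosome carried peaks, from 435 on X to 1320 on chromosome I. Peaks were narrow, with a median width of 538 bp (quartiles 427 and 705 bp), although 184 were 2 kb or wider and the widest reached 11819 bp. The median score was 229.53 (quartiles 104.4 and 578.865), and 181 peaks had a score of 3100 or more, where the scores reached a ceiling. Score and width rose together across peaks (Spearman's rho 0.835), a relation across peaks of 1 list that are not independent replicates. All values come from 1 peak list, deposited under the 1 ChIP library, so no difference below has a replicate check.

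The first comparison asked how condensin II peaks were distributed between the X chromosome and the autosomes. X is the chromosome to which a different condensin, the dosage compensation complex, is recruited in hermaphrodites. KLE-2 peaks were far sparser on X than on the autosomes. X held 24.6 peaks per Mb against 70.1 on the autosomes, a ratio of 0.350 (95% bootstrap interval 0.279 to 0.431 over 1-Mb windows). X made up 17.7% of the span but carried 7.0% of the peaks, and 1.81% of X was covered by peaks against 4.75% of the autosomes. No random labelling of windows as X gave a ratio as extreme (two-sided permutation test, p = 1e-05, the smallest that the permutations can give). The test treats windows as exchangeable, although windows of the same chromosome share its level of density. Taken as whole chromosomes, X lay farthest from the others among 6, which gives an exact share of 0.167 and cannot reach 0.05.

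The autosomes also differed among themselves. Chromosome III had the densest peaks, with 92.1 per Mb (exact Poisson 95% interval 87.1 to 97.4), followed by chromosome I with 87.6 per Mb (82.9 to 92.4). Chromosomes II and IV held 67.7 and 64.4 peaks per Mb. Chromosome V was the sparsest autosome, with 49.5 per Mb (46.5 to 52.6), and its density was still above that of X (22.31 to 26.98). Over full 1-Mb windows, the mean was 90.5 ± 14.9 peaks on chromosome III (SD, n = 13 windows), 48.9 ± 9.97 on chromosome V (SD, n = 20 windows) and 24.6 ± 11.6 on X (SD, n = 17 windows). The emptiest full window of the genome was on X, between 6 and 7 Mb, with 6 peaks, and the densest full windows held 114 peaks. When each autosome was left out in turn, the X to autosome ratio ranged from 0.319 to 0.374.

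**Figure D1:**
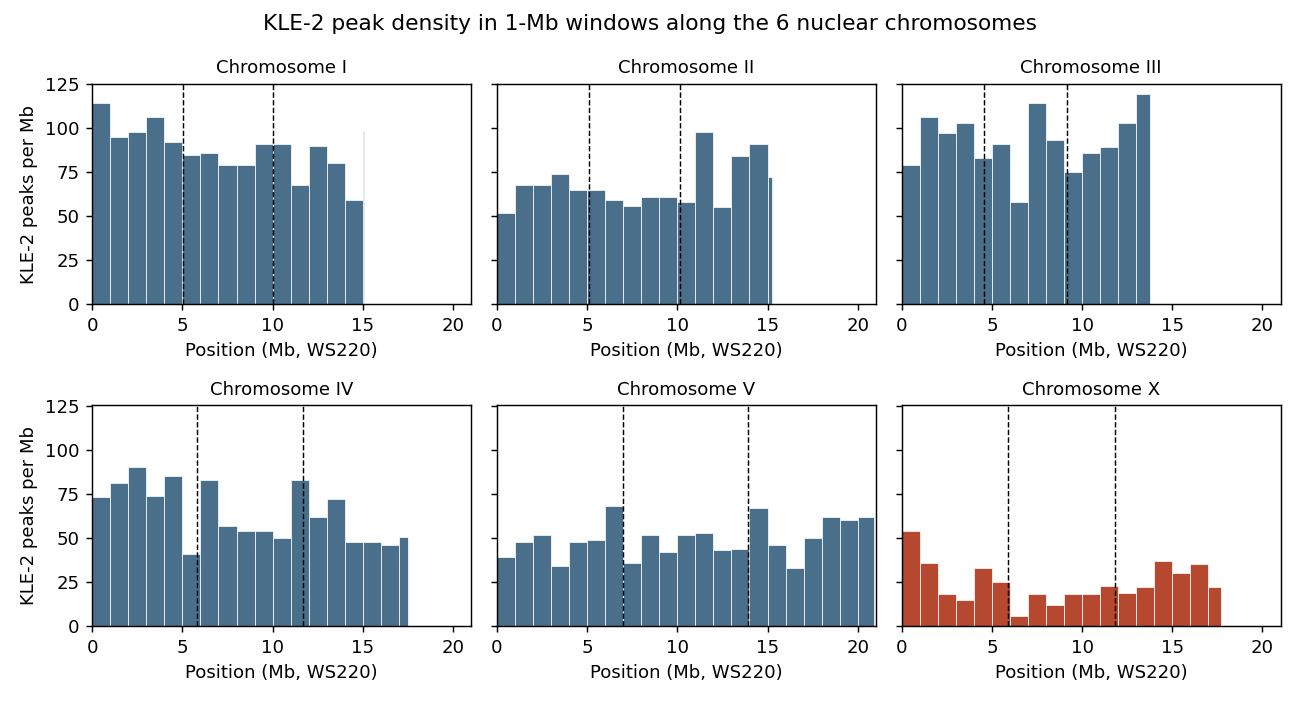
Peaks per Mb (vertical axis) in 1-Mb windows along each nuclear chromosome (horizontal axis, position in Mb on WS220), with X in red, autosomes in blue and dashed lines between the arms (33.3% of the span at each end) and the center. The last bar of each chromosome covers the remaining partial window, and the windows of X range from 6 to 54 peaks per Mb.

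The peaks that X did carry were weaker and narrower at the median, and a larger share of them was at the score ceiling than on the pooled autosomes. Their median score was 167.79 against 235.27 on the autosomes, and their median width was 481 bp against 543 bp. Both differences exceeded those of permuted windows (two-sided permutation test, adjusted p = 1.5e-04 for each). In contrast, 22 of the 435 X peaks were at the ceiling, 5.06% (exact Clopper-Pearson 95% interval 3.20 to 7.56%), against 159 of the 5783 autosomal peaks, 2.75% (2.34 to 3.20%). The difference of 2.31 percentage points also passed the permutation test (adjusted p = 0.0024). Most permuted sets of windows held more peaks than X, so their differences can spread less and these adjusted p-values can be too small. The tests of score, width and ceiling share also treat windows as exchangeable, although windows of the same chromosome may share a level. Single autosomes ranged from 1.497% at the ceiling on chromosome III to 2.90% on II (1.97 to 4.12%), 3.48% on V and 4.17% on IV (3.08 to 5.51%). The intervals of II, IV and V overlap that of X. By score, the X to autosome ratio of peak density was 0.443 among the 1555 peaks with the lowest scores, 0.422 and 0.276 in the next classes of 1554 peaks each, and 0.266 among the 1555 peaks with the highest scores. Among ceiling peaks alone it was 0.645 (95% bootstrap interval 0.351 to 1.03), which did not pass the permutation test (p = 0.078).

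**Figure D2:**
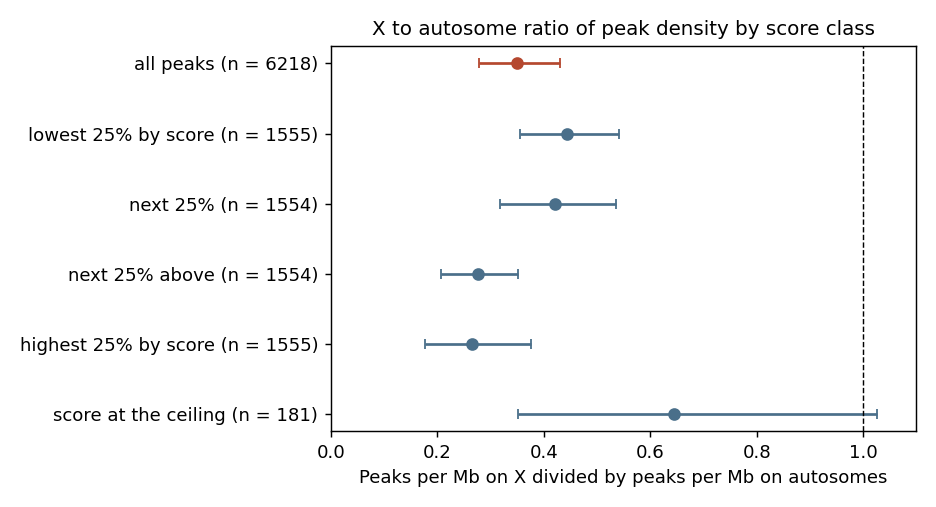
Ratio of peaks per Mb on X to peaks per Mb on the autosomes (horizontal axis) for all peaks, for classes of 25% of the peaks by score and for peaks at the score ceiling (vertical axis), with bars for the 95% bootstrap interval over 1-Mb windows and a dashed line at equal density. The ratio was 0.350 for all peaks and 0.645 at the ceiling, where the interval reaches 1.03.

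The second comparison set chromosome arms, which on the autosomes of this species are richer in repeats and recombine more, against the centers, which are gene-dense there. Peak density was higher in the arms on 6 of 6 chromosomes, by a mean of 7.72 ± 5.13 peaks per Mb (SD, n = 6 chromosomes; two-sided exact sign-flip permutation test, p = 0.03125, the smallest possible). The excess was modest on the autosomes, where the arm to center ratio ran from 1.02 on chromosome IV to 1.25 on chromosome II. These comparisons pool the left and right arms of each chromosome. On chromosome I the right arm was sparser than the center (78.228 against 84 peaks per Mb), and so it was on IV (54.021 against 63.454). On these chromosomes only the left arm exceeded the center. On X the ratio was 1.86, with 30.1 peaks per Mb in the left arm, 15.6 in the center and 27.9 in the right arm. Among the 3107 peaks with a score above the median, density was lower in the arms on all 5 autosomes, with ratios of 0.854 to 0.984, and higher in the arms on X, with a ratio of 2.17. The mean difference among these stronger peaks was -1.56 peaks per Mb (exact p = 0.4062). The 181 ceiling peaks within this set were again denser in the arms on 6 of 6 chromosomes, by a mean of 0.975 ± 0.371 peaks per Mb (SD, n = 6 chromosomes; exact p = 0.03125). Among the 3111 weaker peaks, arms exceeded centers on 6 of 6 chromosomes, with ratios from 1.17 on chromosome IV to 1.70 on X. On X, the arm excess was 7.11 peaks per Mb for weaker and 6.35 for stronger peaks. With arms of 25% at each end, chromosome V changed direction and the test over all peaks gave an exact p of 0.0625. With covered bases in place of peak number, arms were higher on 4 of 6 chromosomes, III and IV changed direction, and the mean difference of 4.28 kb per Mb did not pass the test (exact p = 0.1875).

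**Figure D3:**
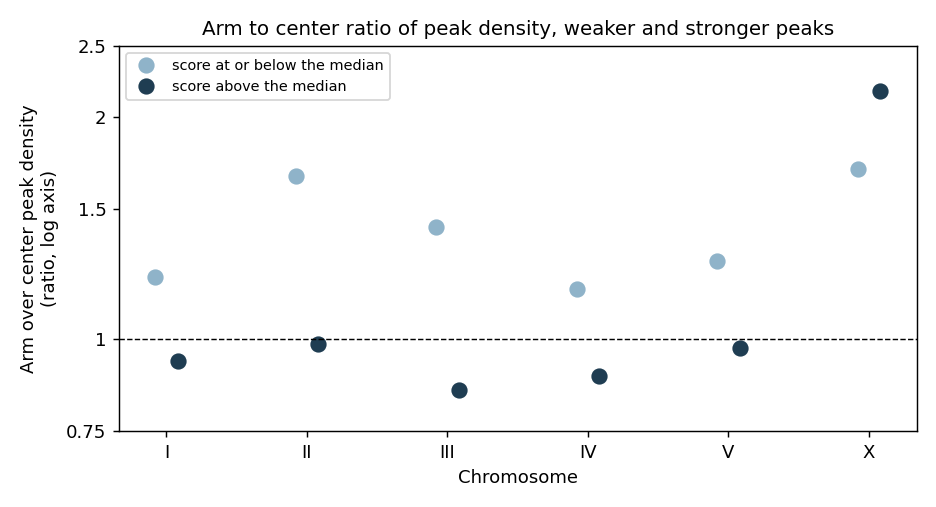
Ratio of peak density in the arms (33.3% of the span at each end) to that in the center on a log axis, for each nuclear chromosome, for peaks with a score at or below the median (light) and above it (dark); the dashed line marks equal density. Stronger peaks lie below the line on the 5 autosomes and at 2.17 on X, and weaker peaks lie above it on 6 of 6 chromosomes.

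The third comparison asked whether peaks were spaced evenly. They were not: 2769 of the 6218 peaks, 44.5%, had another peak within 2 kb, against a mean of 25.3% and a highest value of 28.1% in 10000 random placements (two-sided permutation test by random placement, p = 2e-04, the smallest that the placements can give). The median gap between neighbouring peaks was 6.06 kb on the autosomes and 23.5 kb on X. The longest stretch with no peak was 445 kb on X (6296850 to 6742019), and the longest on an autosome was 208 kb on chromosome V (411370 to 619065). After peaks within 500 bp of each other were merged into 5506 regions, 31.7% still had a neighbour within 2 kb, against a random mean of 22.7%.

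The peak with the highest score lay on chromosome II (13820918 to 13822336, score 3219.64). It was followed by a peak on chromosome IV (2828370 to 2830723, score 3212.27), one on chromosome I (6723768 to 6724814, score 3142.75) and one on chromosome V (10896963 to 10897667, score 3135.63). Chromosome IV held another 3 of the 10 peaks above the ceiling value, at 3050123 to 3051138, at 11913423 to 11915653 and at 15895565 to 15896361. The remaining ones were on chromosome III (1299709 to 1303241), on chromosome II (13520404 to 13522522) and on X (442647 to 444081, score 3100.8). The next 15 named peaks tied at a score of 3100 and were the widest there. They included an 11207-bp peak that ended the list on chromosome I (15060171 to 15071377), at the end of the chromosome that carries the large ribosomal RNA gene array. On chromosome V they comprised peaks of 9493 bp (7915650 to 7925142), 6938 bp (17119818 to 17126755), 6676 bp (3434538 to 3441213), 6104 bp (9338477 to 9344580) and 5329 bp (10018239 to 10023567). Chromosome III contributed peaks of 7809 bp (6566715 to 6574523), 6744 bp (2496579 to 2503322) and 5203 bp (2077524 to 2082726). Chromosome II contributed peaks of 5713 bp (693595 to 699307) and 5124 bp (11756815 to 11761938), and chromosome I a further peak of 5867 bp (13609894 to 13615760). The 3 tied peaks on X were all in its left arm, at 109087 to 114408, at 289745 to 295425 and at 2057653 to 2063974. The genes at these positions were not analysed here.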

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

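The alternatives that used the weaker peaks (score at or below the median), the ceiling peaks, one autosome left out, the autosomes alone, merging in the spacing test and placement within 1-Mb windows were chosen after seeing the data. The sparse peaks on X kept their direction in 13 of 13 alternatives and passed the test in 12, with ratios from 0.271 among peaks with a score above the median to 0.645 among ceiling peaks, the alternative that did not pass (permutation p = 0.078; 22 peaks on X). Part of that count was fixed in advance. Window size leaves the ratio itself unchanged, and leaving out an autosome could not reverse the direction, since each autosome was denser than X. The arm excess was the least stable result and passed the test in 4 of 8 alternatives. It reversed to -1.56 peaks per Mb among peaks with a score above the median. It stayed positive but no longer passed with arms of 25% at each end (7.12 peaks per Mb, exact p = 0.0625), with covered bases in place of peak number (4.28 kb per Mb, exact p = 0.1875, positive on 4 of 6 chromosomes) and on the autosomes alone (6.57 peaks per Mb, where 5 chromosomes cannot give an exact p below 0.0625). Apart from that limit, the cause was not tested. The close spacing of peaks passed in 4 of 4 alternatives. The alternatives for gene starts, tRNA genes, annotation classes and gene lists were not run, because no annotation of WS220 was used here. No paired analysis was possible because the ChIP and input groups hold 1 library each and only the ChIP library has values here. Leaving out a replicate was not possible for the same reason. Read depth is unknown, so peaks below the authors' threshold, on X or elsewhere, may be missing. The X to autosome ratio of 0.271 among peaks above the median score cannot settle this, since a lower signal scale on X would also lower it.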

Other observations

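The permutation test over windows and the merging of peaks for X were set before the data were examined; the bound on the merged ratio and the other tests in this part, including placement within 1-Mb windows, were chosen after results had been seen. Peaks lay at the very start of the chromosomes. The first peak began at base 1 on 6 of 6 nuclear chromosomes, where the assembly starts with telomeric sequence. These peaks had scores of 1630.04 on chromosome I, 508.03 on II, 363.73 on III, 421 on IV, 1266.16 on V and 814.28 on X, which were between the 63.6th and the 91.8th percentile of all peaks. The last peaks had a score of 3100 on chromosome I, 1004.57 on III and 585.75 on II, but only 103.05 on IV, 96.2 on V and 70.38 on X. How far the last peaks lie from the ends of the assembly was not examined, since chromosome length was taken from those peaks. The widest peak in the list, 11819 bp on chromosome I (10207544 to 10219362), had a score of just 278.87, against 3100 for the peak next to it in width.

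Some stretches were crowded. Of 1005 windows of 100 kb, 6 held more peaks than 20, the 95th percentile of the fullest window in random placements. The fullest was on chromosome III between 7.4 and 7.5 Mb, with 28 peaks covering 37.5 kb (permutation test by random placement, p = 1e-04, the smallest that 10000 placements can give). Windows with 25 peaks lay on chromosome I (2.0 to 2.1 Mb), chromosome III (1.9 to 2.0 Mb), chromosome IV (3.3 to 3.4 Mb) and chromosome V (6.0 to 6.1 Mb), and a window with 22 on chromosome IV (2.6 to 2.7 Mb). Of the 41 windows without a peak, 26 were on X, which has 178 of the windows. Ceiling peaks on X lay mostly toward its ends, with 10 in the left arm, 2 in the center and 10 in the right arm. All peaks on X also lay mostly there, with 178, 92 and 165 in the same order. Ceiling peaks were denser in the arms on 6 of 6 chromosomes, so this was not particular to X.

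X carried 0.350 times the autosomal peak density. Chance placement of windows was argued against by the permutation test (p = 1e-05) only if windows are exchangeable. Windows of the same chromosome share its level of density, and over whole chromosomes the exact share of 0.167 cannot argue against chance. Splitting of broad autosomal regions with gaps of up to 500 bp was argued against as the whole cause. After merging at that distance the ratio was 0.369 (95% bootstrap interval 0.295 to 0.453). Splitting with wider gaps was not tested by merging. For one lower signal scale over the whole of X, the tables point both ways. Among peaks under the score ceiling, the X to autosome ratio of those above the median score was 0.579 times that of the weaker peaks (95% bootstrap interval 0.450 to 0.714), the direction such a scale would give. At the ceiling the ratio was 2.58 times that of the other peaks above the median score (1.52 to 3.93), which goes against it, but how far those sites lie above the ceiling is hidden, so it stays open. Gene content, mappability and the amount of condensin II on X also stay open, and no biological explanation was tested. Gene content was not tested because no annotation of WS220 was used here. The design also holds 1 kind of animal, so no comparison between kinds of animals was possible.

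On the autosomes the arm excess lay among peaks at or below the median score, while stronger peaks had arm to center ratios of 0.854 to 0.984. On X, both sets were denser in the arms, by 7.11 peaks per Mb for weaker and 6.35 for stronger peaks (ratios 1.70 and 2.17), and so were the 181 ceiling peaks over 6 chromosomes, by 0.975 peaks per Mb. Splitting of broad regions with gaps of up to 500 bp is argued against as the whole cause of the larger excess among weaker peaks. After merging at that distance, the arm excess in peaks per Mb was still larger among the weaker peaks on 6 of 6 chromosomes. That count is not independent of the values above. Merging did lower the mean arm excess over all peaks from 7.72 to 5.51 peaks per Mb. It fell from 5.37 to 1.09 on chromosome I and from 4.88 to 1.72 on V, but rose from 1.37 to 1.63 on IV. Part of the excess over all peaks may therefore come from splitting. Splitting with wider gaps was not tested by merging. Repeats in the arms, which might give weak peaks from reads that align to several places, and real weak binding there stay open, since neither reads nor the genome sequence were analysed here.

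Peaks lay close to one another more often than random placement gives. Splitting with gaps of up to 500 bp is not the whole cause. After merging at that distance, 1744 of 5506 regions had a neighbour within 2 kb, against at most 1409 in 10000 placements. Regions split by wider gaps would stay apart after merging and still count as neighbours, so the test cannot decide about them. Differences in density between 1-Mb windows are not the whole cause either. In the list, 2769 peaks had a neighbour within 2 kb, against at most 1793 when peaks were placed at random inside their own window. Clustering on a finer scale, such as that of genes and their promoters, may account for the rest and was not tested.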
